A study of Caenorhabditis elegans with 21 samples.

How the data were processed

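RNA was measured in whole day 1 adult Caenorhabditis elegans of 7 genotypes, with 3 replicate libraries of each, 21 in all. Per the labels, animals came from a 4-hour egg-lay, were kept at 15 °C until the L4 stage and then at 20 °C for another 20 to 24 hours, and plates with males were thrown away. Poly(A) RNA with an integrity number of at least 8 was made into libraries, 4 libraries shared a lane, and reads came from a paired-end run of 100 cycles.

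Per the labels, the authors called bases with CASAVA 1.8.2, aligned the reads with TopHat2 2.0.9 and quantified them with Cufflinks 2.1.1. The genome build and the gene annotation behind that step are not given in the sources used here. The deposited tables hold expected counts of fragments and FPKM (fragments scaled for transcript length and for the library) for 33886 loci. A total of 86.3% of the count values are whole numbers within a tolerance of 1e-09, and the others carry fractions, as counts do when a fragment is divided among transcripts. Over the 21 libraries, the log2 FPKM per count followed minus the log2 of the 75th percentile of the counts (r = 0.991) more closely than minus the log2 of the library total (r = 0.409), so the deposited FPKM values are scaled to the upper part of the count distribution and not to the library total. FPKM sums per library ran from 756420 to 1816122. Both tables were read in full, with 0 columns left out.

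A locus merges genes that overlap, and 1954 loci hold more than 1 protein-coding gene. These carry 41.5% of all counts, and 1930 of the 12091 loci tested (16%) are of this kind. Such a locus is named here with all its genes, separated by a slash, and its change cannot be assigned to 1 of them. The 3 entries of the count table that are not loci and the 300 loci without a gene name were left out. The unnamed loci held 1.06% to 1.54% of the counts of a library. Of 40230 gene names in the tables, 38348 (95.3%) matched the gene names of Ensembl release 115 (WBcel235), which supplied gene types and positions.

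Counts were rounded to whole numbers and compared with edgeR 4.0.16 in R 4.3.3. All 21 libraries went into 1 quasi-likelihood model with a term for each genotype, TMM scaling and the filterByExpr filter, which left 12091 loci, called genes below. The common biological coefficient of variation was 0.346. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called changed. All p-values of genes are 2-sided and adjusted in this way. The log2 fold changes come from the model and are given with their standard errors (SE), and counts scaled to the library size (counts-per-million, CPM) with the standard deviation (SD) of 3 libraries. Log2 CPM used a prior count of 2. Intervals and standard errors cover the spread between libraries or counting error and not errors in how reads were assigned to genes.

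The comparisons were daf-2(e1370) against N2 wild-type, each of the 5 daf-16;daf-2 genotypes against daf-2, the 2 daf-16a mutations against each other, mg54 against mu86, the mean of the 2 daf-16a mutations against tm6659, mu86 against N2, and a test of additivity (the mg54 effect minus the sum of the mean daf-16a effect and the tm6659 effect). Genes higher in daf-2 than in N2 and lower in mu86 than in daf-2 are called class I here, and genes that moved the opposite way in both are called class II. For each class and library, the mean log2 CPM was placed on an axis from the daf-2 mean (0) to the mu86 mean (1). Groups of positions were compared with exact 2-sided permutation tests, 20 in all, with Benjamini-Hochberg adjustment over the 20.

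A set of 37 gene lists was written before the data were examined. They cover known targets of the DAF-16 protein, stress defence, detoxification, immunity, metabolism, protein synthesis and folding, insulin signalling, the cuticle, and markers of tissues, stages and the germ line. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry. The p-values of lists are from camera at the preset correlation unless stated, adjusted over the 37 lists of a comparison. Members called changed are counted over all genes tested and also adjusted over the list alone. The genes named in the text were set by a rule from the same time. It takes daf-16 and daf-2 in every library, then the changed genes with the largest fold changes in each direction (10 for daf-2 against N2 and for mu86 against daf-2, 5 for the others) among those with a public gene symbol of letters and a number, a mean of at least 2 CPM over the 21 libraries and no overlap between the replicates of the groups. It also takes up to 4 changed members of a list with the smallest p, and the genes of the lists of known DAF-16 targets. Genes outside this rule are named as such.

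Replicate numbers are shared by the 7 genotypes, and the labels do not say that they mark a shared day. A model with the replicate number as an added term is given beside a comparison where the 2 libraries of every number correlated above 0.1 after their genotype means were removed. That was the case for every comparison except daf-2 against N2 (r = -0.09, 0.53 and 0.41) and mu86 against daf-2 (r = -0.32, 0.21 and 0.47).

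The other settings tried were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no count filter, a minimum mean of 2 CPM, the deposited FPKM values with 1 or 0.1 added before taking logs, an adjusted p under 0.01, a log2 fold change of at least 1, a model of the compared groups alone, the replicate term, and leaving out each library in turn. For the axis positions they also included medians over the class genes, classes defined by 2-fold changes or on held-out replicates, and the lists of known DAF-16 targets in place of the classes. For the correlations between mutants they included fold changes taken against different daf-2 libraries. Added after the data were seen were a model with the mean of the sperm list as a covariate and a model without the libraries numbered 2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

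The edgeR test was run on data simulated to resemble mu86 against daf-2, with 100 genes changed at each size. It recovered 39% of 2-fold and 71% of 4-fold changes, with 3 false calls. With the smaller spread left after the replicate term, these were 55%, 89% and 14. Of unchanged genes 5% had p under 0.05, more than between the daf-16a mutations, so real recovery may differ. Where all libraries of a group hold 3 counts or fewer for a gene, no fold change is given.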

Results

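Poly(A) RNA was counted in whole day 1 adults of 7 genotypes, with 3 libraries of each. They were N2 wild-type, daf-2(e1370), and daf-2(e1370) with 1 of 5 mutations in daf-16. The daf-2 gene encodes the insulin/IGF-1-like receptor of the worm, and e1370 lowers its activity. The daf-16 gene encodes a FoxO transcription factor that acts when daf-2 signalling is low, and it makes several protein isoforms. Per the labels, mu86 is a null mutation, mg54 affects the a and f isoforms, tm5030 and tm5032 are independent daf-16a mutations, and tm6659 is a daf-16f mutation. The design asks how much of the daf-16-dependent response in daf-2 animals each isoform carries. Libraries held 30384772 to 47170645 fragments, and the 10 largest loci took 8.4% to 11% of a library.

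The daf-16 locus (chromosome I, 10750498 to 10776703) was measured in all 21 libraries. Its level was 187 ± 5.06 CPM in N2 and 163 ± 18.6 CPM in daf-2 (SD, n = 3 each, as for all CPM values below). It was lower in mg54, at 94.2 ± 0.212 CPM (log2 change against daf-2 -0.79 ± 0.11 SE, adjusted p = 0.000191), and in tm6659, at 57.7 ± 11 CPM (-1.50 ± 0.11, adjusted p = 1.49e-06). All 3 libraries of each of these genotypes lay below every daf-2 library. In tm5030 (144 ± 11.1 CPM) and tm5032 (165 ± 13.7 CPM) no change was detected (adjusted p = 0.886 and 0.999). The libraries labelled daf-16(mu86);daf-2 held 154 ± 11.7 CPM (145, 150 and 167 CPM), a log2 change of -0.08 against daf-2 (adjusted p = 0.796). A count for the whole locus does not show which part of the gene the fragments came from, so, although mu86 is known as a large deletion in daf-16, the counts show neither this lesion nor whether the label is right. In what follows, mu86 stands for the libraries with this label. The daf-2 locus (chromosome III, 2994514 to 3040846) held 136 ± 8.38 CPM in N2, 173 ± 12.3 in daf-2, 115 ± 12.6 in mu86 and 116 ± 7.11 in mg54. Its transcript was higher in daf-2 than in N2 (log2 change 0.34, adjusted p = 0.0485), but lower there with the deposited FPKM values (-0.26 with 1 added and -0.27 with 0.1 added). It was lower in mu86 (-0.59, adjusted p = 0.00246) and mg54 (-0.58, adjusted p = 0.0029) than in daf-2.

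**Figure D1:**
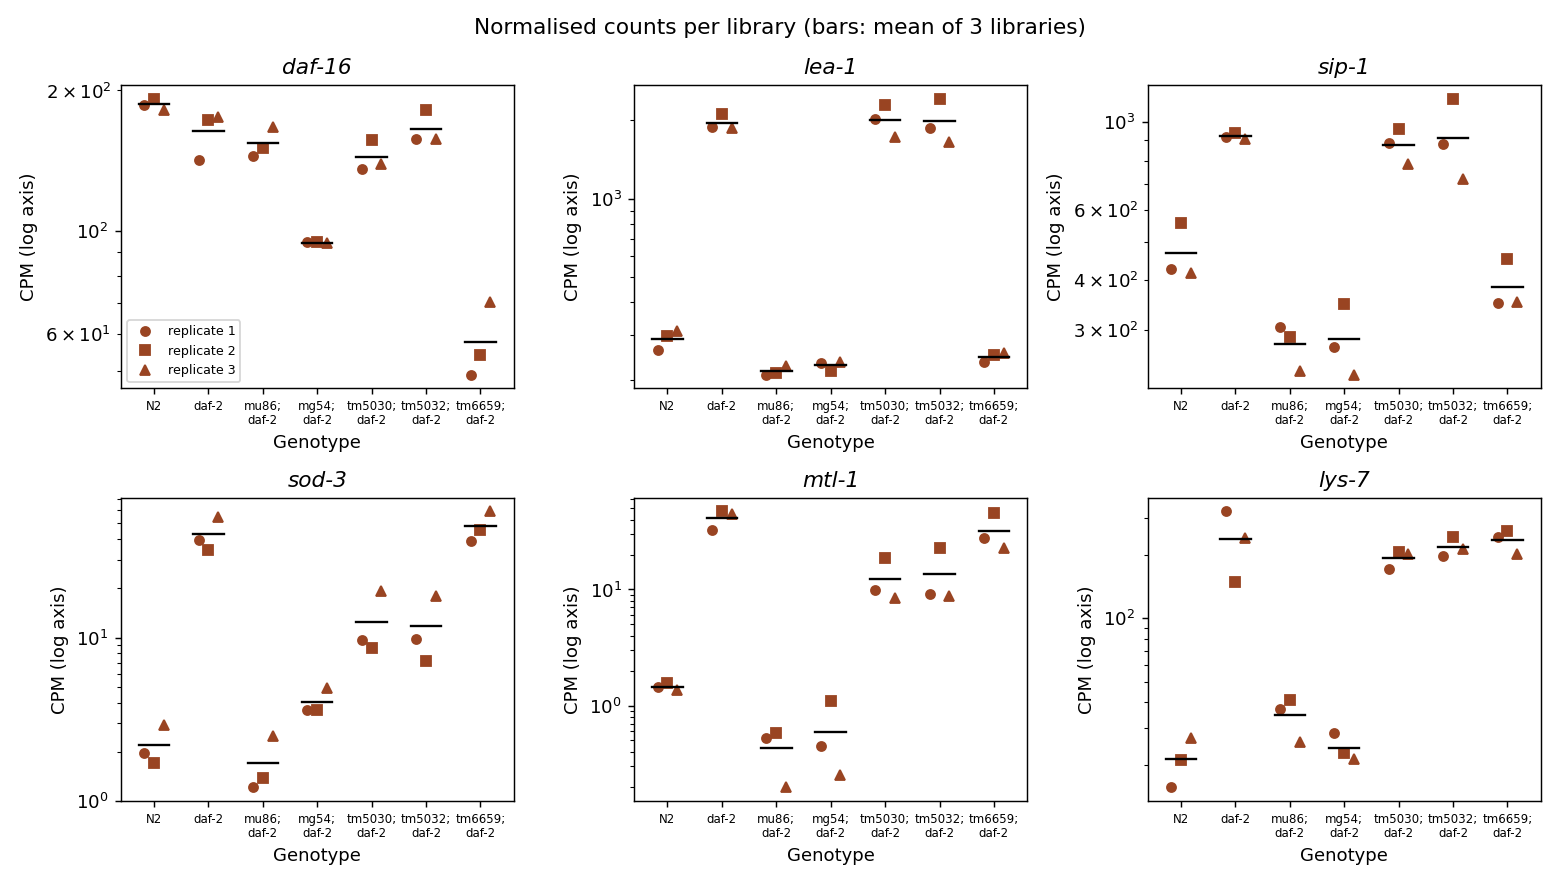
CPM (counts scaled to library size, log axis) of daf-16, lea-1, sip-1, sod-3, mtl-1 and lys-7 in each of the 21 libraries, by genotype, with a bar at the mean of 3 libraries. The lea-1 mean fell from 1952 CPM in daf-2 to 247 CPM in tm6659.

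Between daf-2 and N2, 2018 of 12091 genes changed (edgeR), with 1312 higher and 706 lower in daf-2, and 966 of them at least 2-fold. The lipase lipl-1 rose 111-fold (log2 6.79 ± 0.86 SE, adjusted p = 3.78e-05) and lipl-2 rose 47.4-fold (5.57 ± 0.39, adjusted p = 1.04e-07). The neighbouring genes pud-3 and pud-4, named for proteins that accumulate in daf-2 animals, rose 91.5-fold (adjusted p = 6.72e-08) and 66.4-fold (adjusted p = 1.06e-07). Further large increases were in the transthyretin-like gene ttr-26 (log2 5.50 ± 0.49, adjusted p = 1.17e-06), dod-3 (5.43 ± 0.46, adjusted p = 5.2e-07), icmt-1 (5.53 ± 0.76, adjusted p = 8.3e-05), sdz-24 (5.31 ± 0.53, adjusted p = 3.64e-06) and pals-26 (5.08 ± 0.42, adjusted p = 4.92e-07). The esterase gene cest-1.1 went from 0.0192 ± 0.0169 CPM in N2, with at most 1 fragment in a library, to 13.6 ± 5.54 CPM in daf-2 (adjusted p = 4.92e-07). Large decreases were found in dod-24 (-3.41 ± 0.47, adjusted p = 8.24e-05), the cuticlin-like gene cutl-18 (-3.10 ± 0.44, adjusted p = 1e-04) and the stearoyl-CoA desaturase gene fat-7, which went from 214 ± 33.8 to 28.9 ± 4.48 CPM (adjusted p = 2.78e-06). Also lower were the acyltransferase-like gene oac-20 (-2.46), the collagens col-135 (-2.42) and sqt-3 (-2.37), the phosphatase-like gene pho-8 (-2.38), ugt-53 (-2.33), the lectin gene clec-10 (-2.31) and plep-1 (-2.01), with adjusted p from 2.65e-05 to 0.0056.

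Several lists of stress defence and detoxification genes had more higher than lower members in daf-2. Of these, the known DAF-16 targets and the cytochrome P450s also passed with an estimated correlation, while small heat shock proteins (adjusted p = 0.196) and UDP-glucuronosyltransferases (adjusted p = 0.0505) did not pass as lists. In the list of known targets that DAF-16 raises, 14 of 19 were higher and 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 2.94e-24, and adjusted p = 0.000601 with an estimated correlation). That list was drawn up from earlier work on such mutants, so its direction is not independent of it. It includes the manganese superoxide dismutase sod-3 (log2 4.28 ± 0.42, adjusted p = 3.1e-06), the metallothionein mtl-1 (4.84 ± 0.54, adjusted p = 1.14e-05), the ferritin ftn-1 (4.48 ± 0.37, adjusted p = 4.34e-07) and lea-1 (2.76 ± 0.13, adjusted p = 1.37e-09), a member of a protein family tied to survival of drying. The sod-3 counts carry fractions and mtl-1 appears in 2 loci, so their exact levels are less certain. Superoxide dismutases, catalases and peroxiredoxins were higher in 5 of 8 (5 adjusted over the list alone; adjusted p = 0.000773, and adjusted p = 0.0592 with an estimated correlation). Metallothioneins, ferritins and cadmium-response genes were higher in 4 of 8 and lower in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.0543 with an estimated correlation). With FPKM values and 1 added, the medians of these 2 lists turned negative (-0.28 and -0.07, beside -0.48 for all genes). Among 43 cytochrome P450 loci, 23 were higher and 1 lower (26 and 1 adjusted over the list alone; adjusted p = 5.07e-06, and adjusted p = 0.0169 with an estimated correlation), with cyp-35B1 higher (6.11 ± 0.61) and cyp-13A2 lower (-2.88 ± 0.32). Glutathione S-transferases were higher in 14 of 36 and lower in 1 (17 and 1 adjusted over the list alone; adjusted p = 5.07e-06, and adjusted p = 0.277 with an estimated correlation), gst-10 among them (2.51 ± 0.26). Lysozymes, saposin-like proteins and other antimicrobial genes were higher in 20 of 47 and lower in 1 (24 and 2 adjusted over the list alone; adjusted p = 3.38e-12, and adjusted p = 0.0543 with an estimated correlation), with abf-2 at 5.12 ± 0.35 and lys-7 at 3.48 ± 0.26.

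Among the lists of metabolic genes some had more higher than lower members, and those of ribosomal proteins, proteasome subunits and chaperones had more lower members. None of the lists in this group passed with an estimated correlation, and fatty acid desaturases and synthesis did not pass at all (adjusted p = 0.544). Lipases and beta-oxidation genes were higher in 13 of 34 (15 higher and 3 lower adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.0592 with an estimated correlation), among them lipl-4 (1.35) and acox-3 (0.98). The list's median turned negative with FPKM values (-0.21 with 1 added, beside -0.48 for all genes). Genes of glycolysis and gluconeogenesis were higher in 4 of 12 (5 and 2 adjusted over the list alone; adjusted p = 0.0353, and adjusted p = 0.375 with an estimated correlation), including the phosphoenolpyruvate carboxykinases pck-1 (1.73) and pck-2 (1.16). This median too turned negative with FPKM values (-0.32 with 1 added). In the list of glyoxylate, trehalose and glycogen genes 4 of 9 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.183 with an estimated correlation; FPKM median -0.02 with 1 added), with sodh-2 at 4.20 and the glyoxylate enzyme icl-1 at 1.94. Insulin-like peptide genes were higher in 10 of 22 and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.000139, and adjusted p = 0.183 with an estimated correlation), with ins-10 at 3.95 ± 0.59. Cytosolic ribosomal protein genes were lower in 33 of 40 (39 adjusted over the list alone; adjusted p = 3.35e-18, and adjusted p = 0.183 with an estimated correlation), by small amounts such as -0.43 ± 0.06 for rps-27. Proteasome subunits were lower in 10 of 17 (16 adjusted over the list alone; adjusted p = 6.29e-08, and adjusted p = 0.375 with an estimated correlation). Chaperones other than small heat shock proteins were lower in 10 of 12 (11 adjusted over the list alone; adjusted p = 1.27e-09, and adjusted p = 0.0543 with an estimated correlation), with the mitochondrial chaperone hsp-60 at -0.46 ± 0.05. Beside all these groups, the sperm marker list had a mean log2 CPM of 1.37 ± 1 in N2 and 2.93 ± 0.94 in daf-2 (SD, n = 3; exact permutation p = 0.2, 2-sided). Embryo markers stood at 1.75 ± 0.3 in N2 and 0.96 ± 0.08 in daf-2, and oocyte markers at 8.92 ± 0.09 and 8.76 ± 0.12 (exact permutation p = 0.1 and 0.2, where 0.1 is the smallest possible).

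The balance of higher and lower genes depended on the scaling. The share of changed genes that were higher was 65.0% with TMM, 54.8% with RLE (1165 and 960), 50.4% with upper-quartile scaling (1243 and 1221) and 37% with FPKM values and 1 added (366 and 624). FPKM values put the median log2 change of all genes at -0.48 (1 added) and -0.51 (0.1 added), and TMM at 0.08. The share was 54% with DESeq2, 52% with a mean of at least 2 CPM and 41.5% with FPKM values and 0.1 added (442 and 622). FPKM values gave 990 and 1064 changed genes, a model without the libraries numbered 2, added after the data were seen, 1239, and the fit without N2 replicate 2 gave 1237.

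In the libraries labelled daf-16(mu86);daf-2, 1244 genes changed, with 499 higher and 745 lower than in daf-2 and 662 at least 2-fold. Several genes raised strongly in daf-2 fell strongly here. The metallothionein mtl-1 went from 41.5 ± 7.64 to 0.434 ± 0.206 CPM (log2 -6.55 ± 0.60, adjusted p = 1.75e-06) and sod-3 from 42.9 ± 10.7 to 1.7 ± 0.698 CPM (-4.66 ± 0.43, adjusted p = 1.77e-06). The lipases lipl-1 (-5.54 ± 0.79, adjusted p = 0.000161) and lipl-2 (-4.28 ± 0.36, adjusted p = 7.05e-07) fell. So did ftn-1 (-4.16 ± 0.36, adjusted p = 9.38e-07), sdz-24 (-6.46 ± 0.57), bath-26 (-5.38 ± 0.58), pals-26 (-5.12 ± 0.43) and ttr-26 (-4.37 ± 0.46). The esterase gene cest-1.1 was at 0.0842 ± 0.0125 CPM with at most 3 fragments in a library. Among the increases, dod-24 went from 0.826 ± 0.517 to 25.3 ± 8.8 CPM (4.92 ± 0.50, adjusted p = 5.32e-06), and the glycerol-3-phosphate dehydrogenase gene gpdh-1, known for its response to osmotic stress, rose 15.6-fold (adjusted p = 7.28e-06). The aspartyl protease gene asp-17 (4.28 ± 0.55), pho-8 (4.14 ± 0.57), oac-20 (3.61 ± 0.34), cutl-18 (3.38 ± 0.44) and dod-17 (3.43 ± 0.78, adjusted p = 0.00793) rose as well. The collagen genes col-125 (4.91 ± 1.26, adjusted p = 0.0176), col-168 (4.54 ± 1.28, adjusted p = 0.0295) and col-180 (3.71 ± 0.96, adjusted p = 0.0182) rose with a wide spread between replicates, such as 18.3 ± 18.7 CPM for col-125. Under limma-voom col-125 was no longer called (4.72, adjusted p = 0.0772).

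Of the lists tested in mu86 against daf-2, both lists of known DAF-16 targets and the superoxide dismutases and their companions passed also with an estimated correlation. Of 19 known targets that DAF-16 raises, 15 were lower and 0 higher (15 and 0 adjusted over the list alone; adjusted p = 8.08e-35, and adjusted p = 0.000115 with an estimated correlation), with lea-1 at -3.17 ± 0.13, the small heat shock protein gene sip-1 at -1.74 and hsp-12.6 at -1.98. Of 9 known targets that DAF-16 lowers, 4 were higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 7.24e-08, and adjusted p = 0.00812 with an estimated correlation), with dod-22 at 5.09 ± 0.83 and dod-23 at 2.26 ± 0.25. These lists too were drawn up from earlier work on this direction. In daf-2 against N2, the same list had 1 higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.0877). Superoxide dismutases, catalases and peroxiredoxins were lower in 5 of 8 (5 adjusted over the list alone; adjusted p = 7.45e-07, and adjusted p = 0.0111 with an estimated correlation). Metallothioneins and their companions were lower in 3 of 8 (1 higher and 4 lower adjusted over the list alone; adjusted p = 8.49e-05, and adjusted p = 0.0518 with an estimated correlation). Antimicrobial genes went both ways, with 13 of 47 lower, such as lys-7 (-2.78) and spp-2 (-3.26), and 4 higher, such as irg-4 (2.37; 17 lower and 4 higher adjusted over the list alone; adjusted p = 4.59e-06, and adjusted p = 0.222 with an estimated correlation). C-type lectins were higher in 21 of 77 and lower in 12 (24 and 16 adjusted over the list alone; adjusted p = 0.0164 for higher, and adjusted p = 0.559 with an estimated correlation). UDP-glucuronosyltransferases were higher in 10 of 47 and lower in 4 (10 and 4 adjusted over the list alone; adjusted p = 0.0287, and adjusted p = 0.559 with an estimated correlation), with ugt-53 at 3.36 and ugt-18 at -4.63. The yolk protein genes vit-1 (0.89, adjusted p = 2.62e-06) and vit-4 (0.53) were higher, 2 of 5 vitellogenins (4 adjusted over the list alone; adjusted p = 5.4e-06, and adjusted p = 0.141 with an estimated correlation).

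None of the further lists tested in mu86 and given here passed with an estimated correlation. Glutathione S-transferases were lower in 8 of 36 and higher in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.000167, and adjusted p = 0.393 with an estimated correlation), gst-20 among them (-1.73). Cytochrome P450 loci were lower in 8 of 43 and higher in 2 (10 and 3 adjusted over the list alone), which did not pass as a list (adjusted p = 0.063). Fat breakdown genes were lower in 6 of 34 and higher in 2 (9 and 3 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.181 with an estimated correlation), with lipl-4 at -2.16. Glyoxylate, trehalose and glycogen genes were lower in 4 of 9 and higher in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.0101, and adjusted p = 0.141 with an estimated correlation), with sodh-2 at -3.82. Insulin-like peptides were lower in 6 of 22 (9 adjusted over the list alone; adjusted p = 0.000237, and adjusted p = 0.234 with an estimated correlation), including ins-10 (-3.90) and ins-29 (-3.83). Genes of the insulin and DAF-16 pathway were lower in 4 of 14 (4 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.181 with an estimated correlation), including the kinases pdk-1 (-1.17) and akt-1 (-0.72), while this list had not passed in daf-2 against N2 (adjusted p = 0.814). Ribosomal protein genes were higher in 6 of 40 (25 adjusted over the list alone; adjusted p = 7.24e-08, and adjusted p = 0.462 with an estimated correlation), with rpl-7 at 0.27. Chaperones were higher in 3 of 12 (6 adjusted over the list alone; adjusted p = 0.000506, and adjusted p = 0.257 with an estimated correlation), with hsp-60 at 0.40. The desaturase fat-7, lower in daf-2, was higher in mu86 (2.72 ± 0.28, adjusted p = 5.73e-06). Of the changed genes 40.1% were higher with TMM and 52.3% with upper-quartile scaling (743 and 677). Pharynx markers, a list of another tissue, were higher in 1 of 10 beside these groups (4 adjusted over the list alone; adjusted p = 0.00406, and adjusted p = 0.508 with an estimated correlation), and cuticle collagens were higher in 5 of 117 and lower in 4 (5 and 4 adjusted over the list alone; adjusted p = 0.000506, and adjusted p = 0.559 with an estimated correlation). A model of the 2 groups alone gave 683 genes and FPKM values 679 and 797. Of the models added after the data were seen, the one without the libraries numbered 2 gave 611 and the one with the sperm covariate 2941.

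Genes that moved 1 way in daf-2 and back in mu86 made up a large part of the daf-2 response. Of the 1312 genes higher in daf-2, 609 (46.4%) were lower in mu86 (class I), where independent lists would share 80.8, and 3 were raised further. Of the 706 lower genes, 249 (35.3%) were higher in mu86 (class II), where independent lists would share 29.1, and 0 fell further. The daf-2 libraries enter both comparisons, which by itself favours such reversals, so part of the excess may come from them. Simulations of unchanged genes gave at most 0 genes in either class, because they gave almost no calls. In 20 simulations that moved the called effects to random genes and kept the daf-2 libraries shared, 34 to 49 genes fell in class I (34 if independent) and 10 to 22 in class II (6.9 if independent). These simulations called 855 higher and 334 lower genes on average in daf-2 against N2, fewer than the data. In 386 class I and 100 class II genes both changes were at least 2-fold. With daf-2 replicate 1 left out, class I held 400 genes, and without the libraries numbered 2 the classes held 330 and 119. FPKM values gave 270 and 311 class I genes, the groups compared alone 106 class II genes and upper-quartile scaling 445. The sperm covariate gave 1254 and 787 class genes.

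The a/f mutation mg54 came close to mu86. Against daf-2 it changed 1130 genes, with 456 higher and 674 lower, and 603 at least 2-fold. A model of the 2 groups alone gave 469 genes, one without the libraries numbered 2 gave 533, FPKM values 627 and 744, the replicate term 2300 and the sperm covariate 2752. Large decreases were found in sdz-24 (-7.23 ± 0.61, adjusted p = 7.76e-07), mtl-1 (-6.14 ± 0.59, adjusted p = 3.22e-06), lipl-1 (-5.30 ± 0.78, adjusted p = 0.000268) and bath-26 (-4.57 ± 0.55, adjusted p = 3.42e-05). The cest-1.1 gene was at 0.0206 ± 0.0181 CPM with at most 1 fragment in a library. Large increases were found in asp-17 (4.18 ± 0.55, adjusted p = 8.19e-05), col-125 (4.02 ± 1.22, adjusted p = 0.0475), dod-24 (3.98 ± 0.48, adjusted p = 3.3e-05), pho-8 (3.87 ± 0.57, adjusted p = 0.000237) and gpdh-1 (3.62 ± 0.41, adjusted p = 1.79e-05). Known targets that DAF-16 raises were lower in 13 of 19 (15 adjusted over the list alone; adjusted p = 1.29e-36, and adjusted p = 8.22e-05 with an estimated correlation). Those it lowers were higher in 4 of 9, dod-22 among them (5.02 ± 0.83), and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 4.82e-07, and adjusted p = 0.0131 with an estimated correlation). Superoxide dismutases and their companions were lower in 4 of 8 (5 adjusted over the list alone; adjusted p = 2.02e-05, and adjusted p = 0.0318 with an estimated correlation). Pharynx markers were higher in 1 of 10 (4 adjusted over the list alone, and 6 over all genes with the replicate term; adjusted p = 0.00226, and adjusted p = 0.466 with an estimated correlation). Of the class I genes, 518 (85.1%) were lower in mg54 and 0 higher, and of the class II genes 209 (83.9%) were higher. Compared directly, mg54 and mu86 differed in 4 genes (10 with the replicate term, 10 with DESeq2). Only 136 had an unadjusted p under 0.05, fewer than chance gives. The beta-galactosidase-like gene bgal-2 was higher in mg54 (2.87 ± 0.12, adjusted p = 2.46e-10). The ABC transporter gene haf-6 (-2.01 ± 0.12, adjusted p = 5.39e-08) and daf-16 (-0.71 ± 0.11, adjusted p = 0.0277) were lower, as was Y49G5A.1 (-3.91 ± 0.59, adjusted p = 0.0176), which falls outside the rule and was chosen after its values were seen. Without mu86 replicate 1 or any 1 of the mg54 libraries 2 genes remained past the threshold, and with RLE scaling or FPKM values daf-16 was no longer called.

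The daf-16a mutations changed fewer genes than mg54. Against daf-2, tm5030 changed 110 genes (40 higher, 70 lower) and tm5032 changed 126 (59 higher, 67 lower). In both, oac-20 (2.56 and 2.57), pho-8 (2.57 and 2.36), sqt-3 (2.08 and 2.38) and the collagen col-158 (2.44 and 2.36) were higher, and cest-1.1 fell from 13.6 ± 5.54 CPM in daf-2 to 1.16 ± 0.773 and 1.3 ± 0.623 CPM. In tm5030, dod-24 was also higher (2.09 ± 0.45, adjusted p = 0.0351). In the same libraries, the fatty acid and retinol binding protein gene far-3 (-2.91 ± 0.47, adjusted p = 0.00409), pals-26 (-2.07 ± 0.36, adjusted p = 0.00778), msa-1 (-2.01 ± 0.23, adjusted p = 0.000268) and the globin gene glb-1 (-1.95 ± 0.21, adjusted p = 0.00018) were lower. In tm5032, gpdh-1 was higher (2.34 ± 0.39, adjusted p = 0.00523). In those libraries, lipl-1 (-3.43 ± 0.70, adjusted p = 0.0238), the dehydrogenase genes sodh-1 (-2.62 ± 0.60, adjusted p = 0.0474) and sodh-2 (-2.63 ± 0.50, adjusted p = 0.0144) and the amino acid transporter-like gene slc-36.5 (-2.54 ± 0.58, adjusted p = 0.0442) were lower. The dismutase gene sod-3 fell in both (-1.78 ± 0.37, adjusted p = 0.0315, and -1.87 ± 0.37, adjusted p = 0.0205), while lea-1 stayed at 2012 ± 281 and 1985 ± 395 CPM against 1952 ± 137 CPM in daf-2. Compared with each other, the 2 mutations differed in 3 genes, against 55 at an unadjusted p under 0.05 (5 with DESeq2). These fall outside the rule and were chosen after their values were seen. They are W02D9.6 (3.10 ± 0.42, adjusted p = 0.00485) and the locus mec-19/C49G9.2 (1.74 ± 0.21, adjusted p = 0.00349), both higher in tm5030, and ZC373.2 (-1.02 ± 0.14, adjusted p = 0.00485). Without tm5032 replicate 1 or 2, 1 gene remained.

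Known targets that DAF-16 raises were lower in 3 of 19 in tm5030 (7 adjusted over the list alone; adjusted p = 1.65e-06, and adjusted p = 0.123 with an estimated correlation). In tm5032 it was 2 of 19 (6 adjusted over the list alone; adjusted p = 5.37e-05, and adjusted p = 0.199 with an estimated correlation). Known targets that DAF-16 lowers were higher in 1 of 9 in tm5030 (5 adjusted over the list alone; adjusted p = 1.81e-07, and adjusted p = 0.0138 with an estimated correlation, or 0.0625 when the replicate term was added). In tm5032 0 of 9 were called (4 higher and 1 lower adjusted over the list alone; adjusted p = 1.72e-05, and adjusted p = 0.0502 with an estimated correlation). In both, 1 of 5 vitellogenins, vit-1, was higher (0.38 ± 0.08 and 0.41 ± 0.08; 5 adjusted over the list alone in each; adjusted p = 1.81e-07 and 5e-07, and adjusted p = 0.123 and 0.191 with an estimated correlation). Pharynx markers had 0 of 10 called in both (1 adjusted over the list alone in each; adjusted p = 0.000178 and 0.00404 for higher, and adjusted p = 0.464 and 0.804 with an estimated correlation). With the replicate term 2 and 1 of them were called higher. The replicate term gave 455 and 439 changed genes, DESeq2 284 and 267, a minimum mean of 2 CPM 69 and 72, and a model of the 2 groups alone 5 and 6. Of the models added after the data were seen, the one without the libraries numbered 2 gave 23 and 16 and the one with the sperm covariate 880 and 1048. Without daf-2 replicate 1 or 2 or any 1 of the tm5030 libraries, the tm5030 count was 50 to 69 (73 without tm6659 replicate 2), and without any 1 of the daf-2 libraries, tm5032 replicate 1 or tm5032 replicate 3, the tm5032 count was 54 to 83.

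The daf-16f mutation tm6659 changed 21 genes, 5 higher and 16 lower than in daf-2. The desiccation-linked gene lea-1 fell from 1952 ± 137 to 247 ± 9.91 CPM (log2 -2.99 ± 0.13, adjusted p = 4.5e-10), beside 217 CPM in mu86 and 229 CPM in mg54. The small heat shock protein gene sip-1 went from 921 to 385 CPM (-1.26 ± 0.18, adjusted p = 0.00238), beside 877 and 915 CPM in the daf-16a mutants. Also lower were icmt-1 (-4.42 ± 0.71, adjusted p = 0.00964), the ribonuclease H gene rnh-1.3 (-1.68 ± 0.17, adjusted p = 4.75e-05), the phosphatase-like gene pgph-2 (-1.58 ± 0.19, adjusted p = 0.000551) and daf-16 itself (-1.50 ± 0.11, adjusted p = 1.49e-06). The glucuronosyltransferase gene ugt-64 (1.65 ± 0.20, adjusted p = 0.000576) and the ceramide glucosyltransferase gene cgt-2 (0.91 ± 0.15, adjusted p = 0.0114) were higher. The other 3, Y69A2AR.12, F22F1.2 (2.05) and T10D4.6 (0.86), were chosen outside the rule, after their values were seen. In daf-2, ugt-64 and Y69A2AR.12 (0.0586 CPM, too low for a fold change) were at their lowest. The stress genes mtl-1 and sod-3 stood at 31.9 and 47.8 CPM in tm6659, against 41.5 and 42.9 CPM in daf-2. Known targets that DAF-16 raises were lower in 2 of 19, lea-1 and sip-1 (2 adjusted over the list alone; adjusted p = 1e-13, and adjusted p = 0.013 with an estimated correlation, or 0.0619 when the replicate term was added). Cuticle collagens had a median of 0.70 with 0 of 117 called (14 higher adjusted over the list alone; adjusted p = 3.06e-30, and adjusted p = 0.0837 with an estimated correlation). Genes of the insulin and DAF-16 pathway were lower in 1 of 14, daf-16 itself (1 adjusted over the list alone; adjusted p = 5.76e-05, and adjusted p = 0.0233 with an estimated correlation, or 0.0619 when the replicate term was added). The replicate term gave 85 genes, the sperm covariate 177, DESeq2 59, upper-quartile scaling and a minimum mean of 2 CPM 32 each, the 2 groups alone 11, a model without the libraries numbered 2 gave 7, and FPKM values 6 and 5. Without daf-2 replicate 2, tm6659 replicate 1 or tm6659 replicate 2 the counts were 13, 10 and 13.

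On the axis from daf-2 (0) to mu86 (1), the class I genes of the daf-16a mutants lay between the ends and those of tm6659 close to daf-2. The positions were 0.438 ± 0.066 for tm5030, 0.420 ± 0.026 for tm5032, 0.131 ± 0.071 for tm6659 and 0.956 ± 0.058 for mg54 (SD, n = 3 each), and N2 lay at 1.119 ± 0.073. With the known targets that DAF-16 raises in place of the class I genes, tm5030 and tm5032 lay lower, at 0.241 and 0.227, and tm6659 and mg54 at 0.147 and 0.981. Without tm6659 replicate 3 its position was 0.075. For class II genes they were 0.501 ± 0.035, 0.526 ± 0.057, 0.198 ± 0.034 and 0.91 ± 0.019, with N2 at 0.876 ± 0.04. The value for tm6659 was 0.128 with the groups compared alone, 0.121 on held-out replicates and 0.071 with the known targets that DAF-16 lowers. The 6 daf-16a libraries (0.429 ± 0.046) lay above the 3 of tm6659 by 0.298 for class I and by 0.316 for class II. They lay below mg54, by -0.527 and -0.396. Each exact permutation p was 0.0119 (2-sided, the smallest of 84 splits), or 0.0595 adjusted over 20 tests. Only 27 splits keep to the replicate numbers, so a paired p could not be as low. The 2 daf-16a mutations did not differ detectably (exact permutation p = 0.8 and 0.5), and 3 libraries against 3 cannot give a p below 0.1. Called lower were 69 class I genes (11.3%) in tm5030, 64 (10.5%) in tm5032 and 13 (2.1%) in tm6659. The signs matched mu86 in 94.4%, 94.3% and 82.8% of the class I genes, with median log2 changes of -0.53, -0.49 and -0.16 against -1.38 in mu86. These comparisons share the daf-2 libraries on which the genes were selected, and simulated unchanged mutants matched in 55.8%, 55.3% and 56.9% on average (at most 62.9%). In a check chosen after the data were seen, class I was taken from a fit without a daf-2 library, and the mutant library of the same number was set against that daf-2 library. The shares for numbers 1, 2 and 3 were then 93.5%, 93.8% and 78.2% in tm5030, 92.7%, 89.9% and 79.7% in tm5032, and 80.7%, 62% and 75.9% in tm6659, where 57%, 48.6% and 53.9% of all genes were lower. For class II genes 28 (11.2%), 39 (15.7%) and 3 (1.2%) were called. The class I shares were 23.8%, 20.9% and 4.6% with the replicate term, 22.5%, 18.3% and 3.3% with DESeq2 and 26.6%, 25.3% and 7.4% with the sperm covariate. They were 4.8%, 3.3% and 1.2% without the libraries numbered 2, and 1.2% and 1.4% for tm5030 and tm5032 with the groups compared alone. Leaving out 1 library lowered them to 4.5% (tm5030, its replicate 2), 4.2% (tm5032, its replicate 1) and 1.2% (tm6659, its replicate 1). The class genes were selected on the daf-2 and mu86 libraries that set the ends of the axis.

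**Figure D2:**
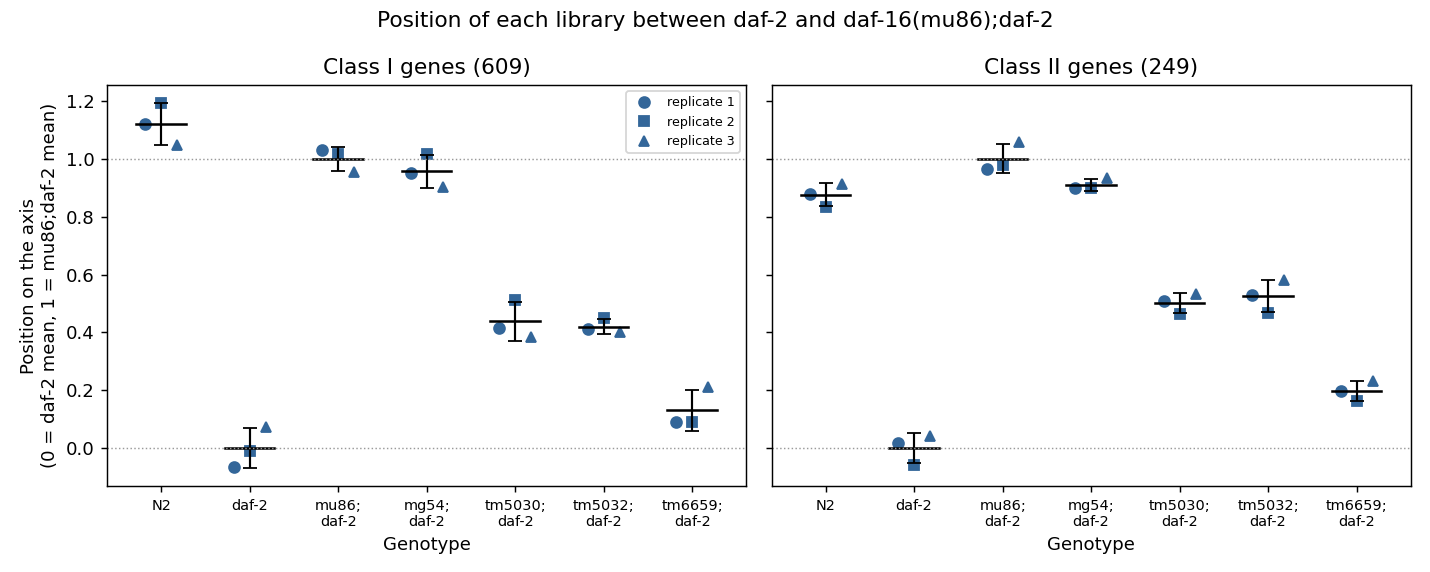
Position of each library on the axis from the daf-2 mean (0) to the mu86 mean (1), from the mean log2 CPM of 609 class I genes and of 249 class II genes, by genotype. Points are libraries and bars are mean ± SD of 3 libraries; the class I mean is 0.956 for mg54.

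Tested directly, the daf-16a mutants (mean of both) and the daf-16f mutant differed in 295 genes, with 142 higher and 153 lower in the daf-16a mutants. Higher in them, so lower in tm6659, were icmt-1 (3.82 ± 0.66, adjusted p = 0.00404), lea-1 (3.02 ± 0.12, adjusted p = 7.44e-11), oac-20 (2.32 ± 0.30, adjusted p = 0.00031), the chemoreceptor-like gene srr-4 (2.22 ± 0.41, adjusted p = 0.00696) and the glutamate-gated chloride channel gene glc-1 (2.15 ± 0.32, adjusted p = 0.00108). The gene sip-1 was higher too (1.22 ± 0.16, adjusted p = 0.000343). Lower in them were lipl-1 (-2.81 ± 0.54, adjusted p = 0.00873), far-3 (-2.63 ± 0.37, adjusted p = 0.000577), slc-36.5 (-2.49 ± 0.46, adjusted p = 0.00641), sodh-1 (-2.1 ± 0.47, adjusted p = 0.0233) and sodh-2 (-2.03 ± 0.39, adjusted p = 0.00914). The stress genes sod-3 (-1.98 ± 0.30, adjusted p = 0.0012) and hsp-12.3 (-0.91 ± 0.18, adjusted p = 0.00987), a small heat shock protein gene, were lower as well. As a list, known targets that DAF-16 raises had 2 of 19 higher and 3 lower (2 and 6 adjusted over the list alone; adjusted p = 0.784). Vitellogenins were higher in the daf-16a mutants in 3 of 5 (5 adjusted over the list alone; adjusted p = 6.51e-08, and adjusted p = 0.137 with an estimated correlation), with vit-6 at 0.42 ± 0.09. C-type lectins were higher in 7 of 77 and lower in 1 (13 and 1 adjusted over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.616 with an estimated correlation), with clec-10 at 2.06 ± 0.26. Cuticle collagens were lower in 4 of 117 and higher in 1 (5 and 1 adjusted over the list alone; adjusted p = 3.56e-07, and adjusted p = 0.627 with an estimated correlation), with col-85 at -4.19 ± 0.33 and col-158 at 1.77 ± 0.36. The replicate term gave 950 genes, the sperm covariate 1677, DESeq2 573, a model of these groups alone 109, and a model without the libraries numbered 2 gave 51. Without tm6659 replicate 1, 2 or 3 the counts were 129, 137 and 180.

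In 53 genes the log2 effects of a and f did not add up to that of the a/f mutation. In 46 of them the mg54 value was lower than the sum of the daf-16a and daf-16f effects, and in 7 it was higher. Only this scale was tested, so a gene can depart here and still be near additive in CPM. The balance was less one-sided with the replicate term (102 lower and 52 higher) and with DESeq2 (90 and 29). The lysozyme gene lys-7 stood at 238 CPM in daf-2, 194 and 218 CPM in the daf-16a mutants and 237 CPM in tm6659, and at 24.3 CPM in mg54 (departure -3.08 ± 0.33, adjusted p = 0.000101). Departures of this kind were found for ftn-1 (-3.03 ± 0.44, adjusted p = 0.00233), lipl-2 (-3.10 ± 0.44, adjusted p = 0.00167), mtl-1 (-4.07 ± 0.67, adjusted p = 0.00752), dod-3 (-3.05 ± 0.52, adjusted p = 0.00907), cyp-35B1 (-3.80 ± 0.70, adjusted p = 0.0138) and spp-2 (-2.83 ± 0.48, adjusted p = 0.00907). The gut esterase gene ges-1 departed by -0.92 ± 0.12 (adjusted p = 0.00122). Transcripts of daf-16 itself departed upward (0.79 ± 0.15, adjusted p = 0.0192). Among known targets that DAF-16 raises, 4 of 19 departed downward (9 adjusted over the list alone; adjusted p = 1.79e-25, and adjusted p = 0.000711 with an estimated correlation). Antimicrobial genes departed downward in 2 of 47 (1 upward and 3 downward adjusted over the list alone; adjusted p = 1.49e-09, and adjusted p = 0.118 with an estimated correlation). The replicate term gave 154 genes, the sperm covariate 176, DESeq2 119, FPKM values 20 and 27, and a model without the libraries numbered 2 gave 13. Without daf-2 replicate 3, mg54 replicate 1 or tm6659 replicate 2 the counts were 33, 32 and 33.

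Between mu86 and N2 there were 184 changed genes, 163 higher and 21 lower, against 3415 at an unadjusted p under 0.05. Of the higher genes 86 were also called higher in daf-2 against N2, 7 were called lower there and 70 were not called. Of the lower genes 12 were also called lower in daf-2, 3 were called higher and 6 were not called. The N2 libraries enter both comparisons, which favours calls in the same direction. The genes pud-3 (4.28 ± 0.38, adjusted p = 2.41e-05) and pud-4 (4.26 ± 0.40, adjusted p = 2.41e-05) were higher in daf-2 and in mu86 than in N2. The infection-response gene irg-4 (2.81 ± 0.27, adjusted p = 2.44e-05), asp-17 (3.04 ± 0.52, adjusted p = 0.00776) and col-180 (4.05 ± 0.98, adjusted p = 0.0472) were higher in mu86 but not called in daf-2 against N2, with asp-17 at 2.379 CPM in N2, 0.9964 CPM in daf-2 and 19.57 CPM in mu86. Lower were bgal-2 (-2.52 ± 0.12, adjusted p = 1.59e-09), sip-1 (-0.76 ± 0.18, adjusted p = 0.0404), the lysozyme gene lys-4 (-0.73 ± 0.15, adjusted p = 0.0253), sac-2 (-0.49 ± 0.10, adjusted p = 0.0253) and the endoplasmic reticulum chaperone gene enpl-1 (-0.28 ± 0.07, adjusted p = 0.0423). Of these, bgal-2 (13.5 CPM in N2, 20.23 in daf-2 and 2.344 in mu86) and sip-1 (467.9, 920.8 and 276.4 CPM) were called higher in daf-2 than in N2, so mu86 lay on the other side of N2 from daf-2. Known targets that DAF-16 lowers were higher in 1 of 9, dod-22 (3.49 ± 0.74; 8 adjusted over the list alone; adjusted p = 3.03e-05, and adjusted p = 0.0463 with an estimated correlation, or 0.242 when the replicate term was added). Cytochrome P450 loci were higher in 6 of 43 (14 adjusted over the list alone; adjusted p = 9.55e-05, and adjusted p = 0.0463 with an estimated correlation, or 0.275 when the replicate term was added). C-type lectins were higher in 8 of 77 (30 adjusted over the list alone; adjusted p = 2.19e-07, and adjusted p = 0.371 with an estimated correlation). Antimicrobial genes were higher in 9 of 47 and lower in 1 (13 and 2 adjusted over the list alone; adjusted p = 0.000156, and adjusted p = 0.474 with an estimated correlation), with lys-1 at 1.09 ± 0.14. The list's median turned negative with FPKM values (-0.03 with 1 added). The sperm list stood at 3.27 ± 0.78 in mu86 and 1.37 ± 1 in N2 beside these groups (mean log2 CPM, SD, n = 3; exact permutation p = 0.1, 2-sided, the smallest possible here). Oocyte markers stood at 8.61 ± 0.19 in mu86 and embryo markers at 1.2 ± 0.51 (exact permutation p = 0.1 and 0.3 against N2). Body wall muscle markers had a median of 0.69 with 0 of 17 called (0 adjusted over the list alone; adjusted p = 0.00238, and adjusted p = 0.619 with an estimated correlation), and pharynx markers had 0 of 10 called (1 higher adjusted over the list alone; adjusted p = 0.00697, and adjusted p = 0.614 with an estimated correlation). With the replicate term 59 of 65 sperm, 16 of 17 muscle and 8 of 10 pharynx markers were called higher and 15 of 19 oocyte and 2 of 12 embryo markers lower (adjusted p = 1.73e-12, 3.76e-05, 0.00542, 5.94e-07 and 0.0298, and adjusted p = 0.507 for each with an estimated correlation), beside 43 lectin, 17 P450 and 18 antimicrobial genes higher. The size and balance of this comparison were not stable. DESeq2 gave 1063 genes, 856 of them lower and 78 shared with the 184, the replicate term 5827, FPKM values 18 and 21, no count filter 109, a model without the libraries numbered 2 gave 10, and a model of the 2 groups alone 2. The median of all genes was 0.13 with TMM and -0.42 or -0.43 with FPKM values. Without N2 replicate 1 or 2 the count was 28, and without mu86 replicate 1, 2 or 3 it was 96, 56 and 42. Leaving out tm5032, tm5030 or mg54 replicate 1 gave 107, 109 and 112, and leaving out tm6659 replicate 1, 2 or 3 gave 117, 116 and 122.

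Fold changes against daf-2 share the daf-2 libraries, so unchanged genes already give a correlation near 0.5 across genes, and genes are not independent replicates. The mu86 and mg54 changes correlated at 0.928 (0.5 simulated), and the changes of the 2 daf-16a mutants at 0.888 (0.502 simulated). Against mu86, the r was 0.668 for tm5030, 0.6 for tm5032 and 0.347 for tm6659 (0.505, 0.504 and 0.504 simulated). With fold changes against different daf-2 libraries these r fell to 0.66, 0.442, 0.375, 0.346 and 0.02, in the order given. Lowered genes in common numbered 598 for mu86 and mg54 (41.5 if independent), 58 for tm5030 and tm5032 (0.39 if independent), and 14 for mg54 and tm6659 (0.89 if independent). Simulations of unchanged genes gave at most 0 for each pair, because they gave almost no calls. Simulations with the called effects moved to random genes and the daf-2 libraries shared gave 16 to 30, 0 to 3 and 0 to 3, with fewer calls than the data, so part of each overlap may come from the shared libraries.

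Replicates of a genotype spread widely on the first principal component (51.8% of the variance), and genotypes separated on the second component (18.9%). On the second component N2, mu86 and mg54 lay at one end, daf-2 and tm6659 at the other, and the daf-16a mutants between them. The libraries that shared a replicate number tended to lie together, since 18 of 21 correlated best with libraries of their own number.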

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

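The comparisons between mutants in this part were planned, while the tests of explanations and the regroupings of libraries were chosen only after the results were seen. In each result below, 2 mutants differed in their effect by a direct test of the difference. The daf-16a mutants and tm6659 differed in 295 genes, with log2 differences of 3.82 for icmt-1, 3.02 for lea-1, 2.32 for oac-20, 2.22 for srr-4 and 2.15 for glc-1, and of -2.81 for lipl-1, -2.63 for far-3, -2.49 for slc-36.5, -2.1 for sodh-1 and -2.03 for sodh-2. The mutants mg54 and mu86 differed in 4 genes, including bgal-2 (2.87), haf-6 (-2.01) and daf-16 (-0.71). The mutants tm5030 and tm5032 differed in 3 genes. In 53 genes the mg54 effect departed from the sum of the daf-16a and daf-16f effects.

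Among the genes lower in tm6659 than in daf-2 were 15 besides daf-16 itself, and 14 of them were also lower than in the daf-16a mutants. In comparisons without a tm6659 library, 13 of 15 (86.7%) were lower in mg54 than in tm5030 and in mu86 than in tm5032. Most of the 15 are class I, lower in mu86 by definition, so this cannot exclude lesions of the tm6659 strain outside daf-16. Loss of daf-16f, shared by those strains per the labels, is a candidate explanation for the 13, such as lea-1 and sip-1. It leaves out dnbp-1 (-0.67 and -0.66 in the daf-16a mutants) and cTel55X.1, lower in tm6659 alone. Nor does it give the level of pgph-2, lower in tm6659 than in mg54 and mu86 (log2 0.94 or more). Whether the f isoform itself or the lower total daf-16 level of tm6659 matters stays open, since the counts do not separate isoforms.

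A few genes changed in a single mutant strain. The gene bgal-2 held 2.34 ± 0.277 CPM in mu86 and 17.8 CPM on average in the other 18 libraries, and haf-6 held 10.5 ± 0.755 CPM in mg54 and 42.1 CPM in the others (SD, n = 3). In tm5032, W02D9.6 and mec-19/C49G9.2 were low and lie 3.9 kb apart on chromosome I. In tm6659, cTel55X.1 was lower (-3.28) and cgt-2 higher (0.91) than in daf-2, 19.7 kb apart on chromosome X, though cgt-2 was not called against every other genotype. Of 10000 random gene sets 0.1% and 10.43% held as many pairs within 25 kb, but this distance was set after the positions were seen, so the shares decide nothing, and a lesion spanning a pair and chance cannot be told apart. A role of the daf-16 mutations themselves in these changes was not tested.

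Libraries were also regrouped. The 6 daf-16a libraries as 1 group against the 3 of tm6659 gave 350 genes, and 2 of the 84 splits gave as many. The other was the 3 libraries numbered 2, with 907 genes, which points to a structure by replicate number. Since the numbers pair these libraries, the 27 splits with 1 library of each number among the 3 were also taken alone, and the real one gave the most genes, the highest other giving 3. For additivity 2 of 100 regroupings gave as many as the real 53, the other giving 437 with all mg54 libraries placed as daf-2. In 100 regroupings that exchanged only libraries of the same number, the real grouping was the 1 with the most genes, and the highest other gave 3. The real grouping was the 1 of 100 with the most class I genes (609, next 588) and class II genes (249, next 241), where the next exchanged N2 and mu86 libraries only. These regroupings mix genotypes that differ, so at the 0.05 level they exclude only that genotype plays no part, and do not test additivity. Each comparison of 3 libraries against 3 has 10 splits, too few for a share under 0.05. There the real split was the 1 with the most genes, and the highest other gave 0 for daf-2 against N2 (2018), mu86 (1244), mg54 (1130), tm5032 (126), tm6659 (21), mg54 against mu86 (4) and mu86 against N2 (184), 2 for tm5030 (110) and 1 for tm5030 against tm5032 (3). For the class I shares of 85.1%, 11.3%, 10.5% and 2.1% it gave 0. Where the replicate numbers pair the libraries, 4 of the splits part every pair, and those other than the real one gave 0 genes in every such comparison.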

How the results depend on the processing

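The model with the sperm list as covariate and the model without the libraries numbered 2 were chosen after seeing the data, and the other settings were planned. No setting turned the direction of a gene called in both fits, and limma-voom and RLE scaling left every count of changed genes, class count, class I share and position within 1.5 times or the replicate spread, though not the share of higher genes, given last in the next paragraph. Of 100 named results, the replicate term kept the call of all 100 and DESeq2 of all 96 it gave a value for, while FPKM values lost 11 (1 added) and 12 (0.1 added), limma-voom 9, no filter 6, upper-quartile scaling 5, RLE 3, a mean of 2 CPM 3, the sperm covariate 2, the groups compared alone 36 and leaving out the libraries numbered 2 39. One of these is pho-8 in daf-2 against N2 (-1.94, adjusted p = 0.0846 without the libraries numbered 2). Reversed were daf-2 transcripts in daf-2 against N2 with FPKM values (-0.26 and -0.27), where the median of all genes moved by a similar amount, and the correlations with tm6659 given last in this part.

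Counts are in the order daf-2 against N2, mu86, mg54, tm5030, tm5032 and tm6659 against daf-2 where all are given. DESeq2 gave 284 for tm5030, 267 for tm5032, 59 for tm6659, 5 for tm5030 against tm5032, 10 for mg54 against mu86, 573 for the daf-16a mutants against tm6659, 1063 for mu86 against N2 (207 higher, 856 lower) and 119 for additivity, with class I shares of 22.5%, 18.3% and 3.3% in tm5030, tm5032 and tm6659. The replicate term gave 5330, 2631, 2300, 455, 439 and 85, then 10 for mg54 against mu86, 950 for the daf-16a mutants against tm6659, 5827 for mu86 against N2 (3373 higher, 2454 lower) and 154 for additivity, with 1005 class I and 556 class II genes and shares of 23.8%, 20.9% and 4.6%. The sperm covariate gave 2941 for mu86, 2752 for mg54, 880, 1048 and 177 for the single-isoform mutants, 5, 13 and 1677 for the comparisons among mutants in the order above, 176 for additivity, 1254 and 787 class genes, shares of 26.6%, 25.3% and 7.4% and a position of 0.465 for tm5032. Without the libraries numbered 2 the counts were 1239, 611, 533, 23, 16 and 7, then 1, 2, 51, 10 for mu86 against N2 and 13 for additivity, with 330 and 119 class genes and shares of 4.8%, 3.3% and 1.2%; fewer libraries lower the power here. The groups compared alone gave 683 for mu86, 469 for mg54, 5, 6 and 11 for the single-isoform mutants, 0, 2 and 109 among mutants and 2 for mu86 against N2, with 106 class II genes and shares of 1.2% and 1.4% in tm5030 and tm5032; the spread is then estimated from fewer libraries. An adjusted p under 0.01 gave 1112, 693, 596, 44 and 50 for the first 5, 2 for mg54 against mu86, 121 for the daf-16a mutants against tm6659, 36 for mu86 against N2, 27 for additivity, 381 and 110 class genes and shares of 7.1% and 6.6%. A log2 fold change of at least 1 left 966, 662, 603 and, for tm6659, 13, then 164 for the daf-16a mutants against tm6659, 74 for mu86 against N2, 386 and 100 class genes and 1.3% for tm6659; both follow from the stricter threshold. FPKM values with 1 added gave 990, 679 and 627 for the first 3, 6 for tm6659, 1 for tm5030 against tm5032, 18 for mu86 against N2, 20 for additivity, 270 class I genes and shares of 22.6% and 21.5% in tm5030 and tm5032. With 0.1 added they gave 1064, 797, 744, 5 for tm6659, 21 for mu86 against N2, 27 for additivity, 311 class I genes and shares of 17%, 17.4% and, for tm6659, 1%. Upper-quartile scaling gave 32 for tm6659 (13 higher, 19 lower) and 445 class II genes, no filter 109 for mu86 against N2, and a mean of 2 CPM 69, 72 and 32 for the single-isoform mutants, 3.9% for tm6659 and a position of 0.363 for tm5032. The position of tm5032 was 0.356 with medians over genes, and with the known DAF-16 targets tm5030 and tm5032 lay at 0.241 and 0.227. For class II, medians gave 0.379, 0.378, 0.154 and 0.865 for tm5030, tm5032, tm6659 and mg54, and the known targets 0.464, 0.389, 0.071 and 0.889. Where no reason is named, the cause was not tested. Higher genes were 36.4% of those called in tm5030, and 48.4% and 55.6% with FPKM values, 53.3% with the sperm covariate, 46.4% with a mean of 2 CPM, 24.1% with limma-voom, 26.1% without the libraries numbered 2 and 0% with the groups compared alone. For tm5032 they were 46.8%, and 61.9% with FPKM values and 0.1 added, 32.2% with limma-voom, 25% without the libraries numbered 2 and 0% with the groups alone. For tm6659 they were 23.8%, and 47.5% with DESeq2, 40.6% with upper-quartile scaling, 13% with limma-voom and 0% without the libraries numbered 2. For additivity they were 13.2%, and 33.8% with the replicate term and 24.4% with DESeq2. With FPKM values the median of all genes was 0.13 against -0.02 for tm5032 and -0.13 against 0.02 for additivity.

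Lists called with an estimated correlation numbered 2 of 18 for daf-2 against N2, 3 of 17 for mu86, 3 of 19 for mg54, 1 of 12 for tm5030, 0 of 13 for tm5032, 2 of 13 for tm6659, 0 of 1 for mg54 against mu86 (superoxide dismutases and their companions), 0 of 10 for the daf-16a mutants against tm6659, 2 of 18 for mu86 against N2 and 1 of 18 for additivity, since most estimates exceed the preset 0.01. With fry they were 2 for tm5030, 3 for tm5032, 3 for tm6659, 0 for mg54 against mu86, 4 for the daf-16a mutants against tm6659 and 1 for additivity, as fry asks another question. With the fold changes taken against different daf-2 libraries, which removes the shared control but leaves fewer libraries, the correlations fell to 0.66 (mu86 and mg54), 0.375 (mu86 and tm5030), 0.346 (mu86 and tm5032), 0.02 (mu86 and tm6659), 0.401 (mg54 and tm5030), 0.386 (mg54 and tm5032), 0.034 (mg54 and tm6659), 0.442 (tm5030 and tm5032), -0.053 (tm5030 and tm6659) and -0.025 (tm5032 and tm6659).

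Leaving out 1 library of the compared groups at a time gave 1237 to 2304 genes for daf-2 against N2 (1237 without N2 replicate 2), 864 to 1115 for mu86 and 815 to 1005 for mg54. It gave 50 to 77 for tm5030 (50, 55, 53, 64 and 69 without daf-2 replicates 1 and 2 and tm5030 replicates 1, 2 and 3), 54 to 90 for tm5032 (57, 67, 83, 54 and 66 without daf-2 replicates 1, 2 and 3 and tm5032 replicates 1 and 3) and 10 to 19 for tm6659 (13, 10 and 13 without daf-2 replicate 2 and tm6659 replicates 1 and 2). The range was 1 to 3 for tm5030 against tm5032 (1 without tm5032 replicate 1 or 2), 2 to 3 for mg54 against mu86 (2 without mu86 replicate 1 or any mg54 library), 129 to 321 for the daf-16a mutants against tm6659 (129, 137 and 180 without tm6659 replicates 1, 2 and 3), 28 to 206 for mu86 against N2 (28 without N2 replicate 1 or 2, and 96, 56 and 42 without mu86 replicates 1, 2 and 3) and 32 to 66 for additivity (33, 32 and 33 without daf-2 replicate 3, mg54 replicate 1 and tm6659 replicate 2). Leaving out a library of another group, which enters only the shared spread, filter and scaling, gave 1921 to 2313 genes for daf-2 against N2, 1136 to 1369 for mu86, 1017 to 1242 for mg54, 73 to 132 for tm5030 (73 without tm6659 replicate 2), 100 to 136 for tm5032, 16 to 21 for tm6659, 3 for tm5030 against tm5032, 4 to 5 for mg54 against mu86, 264 to 320 for the daf-16a mutants against tm6659, 107 to 207 for mu86 against N2 and 50 to 54 for additivity. Class I held 400 to 531 genes (400 without daf-2 replicate 1) and class II 207 to 301. Class I shares ran from 66.8% to 93.9% for mg54, 4.5% to 11.5% for tm5030 (5.8%, 7.1%, 5.1%, 4.5% and 7.2% without the libraries named for its count), 4.2% to 12.7% for tm5032 (5.2% without daf-2 replicate 1, and 4.2%, 4.8% and 5.2% without tm5032 replicates 1, 2 and 3) and 1.2% to 2.5% for tm6659 (1.2% without its replicate 1). Class I positions ran from 0.922 to 0.981 for mg54, 0.391 to 0.458 for tm5030, 0.397 to 0.439 for tm5032 and 0.075 to 0.169 for tm6659 (0.075 without its replicate 3). Genes not called in the single-isoform mutants are not shown to be unchanged.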

Other observations

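The tests of explanations in this part were chosen only after the results were seen, while the gene lists and their tests were planned. Further lists in daf-2 against N2 had members that changed without the list passing. UDP-glucuronosyltransferases were higher in 11 of 47 and lower in 2 (15 and 3 adjusted over the list alone; adjusted p = 0.0505), with ugt-23 at 0.72 and ugt-64 at -1.16, and with FPKM values 3 were higher and 8 lower. C-type lectins were higher in 20 of 77 and lower in 11 (25 and 16 adjusted over the list alone; adjusted p = 0.171), with 8 higher and 12 lower with FPKM values and 1 added. Small heat shock proteins were higher in 3 of 9 (4 adjusted over the list alone; adjusted p = 0.196), namely hsp-12.3 (1.29), sip-1 (0.98) and hsp-12.6 (1.70), though the list's median turned from 0.05 to -0.02 with RLE scaling. Nuclear hormone receptors were higher in 16 of 151 and lower in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.171), with nhr-79 at 1.02 (0 higher and 4 lower with FPKM values and 1 added). Insulin and DAF-16 pathway genes were higher in 5 of 14 and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.814), with the kinases pdk-1 (0.89), akt-1 (0.38) and aak-2 (0.38), and 0 were called with FPKM values. Intestine markers were higher in 3 of 14 (3 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.375 with an estimated correlation), with the gut esterase ges-1 at 1.8 ± 0.1, and neuropeptides in 7 of 80 (2 adjusted over the list alone; adjusted p = 0.0353, and adjusted p = 0.786 with an estimated correlation), with flp-34 at 3.14. Both of these medians turned negative or split with FPKM values.

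Lists that did not pass in daf-2 against N2 were vitellogenins (0 of 5 higher, 1 lower; adjusted p = 0.279), fatty acid desaturases and synthesis (3 of 21 higher, 2 lower; 0.544), cuticle collagens (9 of 117 higher, 2 lower; 0.859), molting markers (2 of 13 higher; 0.279), dauer-associated genes (1 of 5 higher; 0.411), the steroid hormone pathway (1 of 8 higher; 0.966), autophagy and lysosome genes (3 of 28 higher, 1 lower; 0.859), the mitochondrial respiratory chain (2 of 19 lower; 0.279), and markers of body wall muscle (0 of 17; 0.201), pharynx (0 of 10; 0.654), hypodermis (1 of 10 lower; 0.654) and neurons (1 of 20 higher, 1 lower; 0.316). The 4 reference genes had 0 called (2 lower adjusted over the list alone; adjusted p = 0.392). Adjusted over the list alone, counts for these lists were the same except for dauer genes (2 higher, 1 lower), the steroid pathway (0), the respiratory chain (0) and neurons (1 higher). For the fatty acid list, collagens and the steroid pathway the median and mean were positive and the test pointed down, and for autophagy and the reference genes the median was negative and the mean positive. In tm6659 against daf-2, molting markers had 0 of 13 called (2 higher adjusted over the list alone; adjusted p = 4.22e-06, and adjusted p = 0.0704 with an estimated correlation) and hypodermis markers 0 of 10 (2 adjusted over the list alone; adjusted p = 0.000603, and adjusted p = 0.0837 with an estimated correlation), beside the collagens.

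In daf-2 against N2, sperm markers were higher in 1 of 65 (0 adjusted over the list alone; adjusted p = 0.00316, and adjusted p = 0.786 with an estimated correlation), oocyte markers had 0 of 19 called (0 adjusted over the list alone; adjusted p = 0.0182 for lower, and adjusted p = 0.776 with an estimated correlation) and embryo markers 1 of 12 lower (3 adjusted over the list alone; adjusted p = 0.0182, and adjusted p = 0.544 with an estimated correlation).

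The spread of replicates along the first principal component was compared with 6 measures after genotype means were removed (21 libraries, 1e+05 permutations). Library depth did not follow it (r = 0.17, permutation p = 0.51, rho = 0.16, permutation p = 0.54, and r = 0.25 without the 2 farthest libraries). The sperm and oocyte lists went apart (r = 0.99 and -0.97, permutation p = 1e-05 each, 1.5e-05 adjusted, rho = 0.98 and -0.97). Since CPM values are shares of a library, less oocyte RNA would raise the share of all other RNA. The opposite signs therefore do not rule out a different share of germline RNA. Animals at different points of reproductive maturation remain a candidate explanation. The embryo list went down along the component (r = -0.53, rho = -0.51), and muscle and neuron lists went up (r = 0.98 and 0.94). The embryo relation rests in part on the 2 farthest libraries (r = -0.38 without them). Genotype is left out of these values by construction, and a difference in maturation between N2 and the daf-2 strains stays open.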
